A study of Caenorhabditis elegans with 2 samples.

How the data were processed

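Chromatin immunoprecipitation and sequencing had been done in 2 biological replicates of 1 group. The strain, OP471, carries the integrated transgene wgIs471 in an unc-119 mutant background and expresses BCL-11 (the product of bcl-11, F13H6.1) with GFP and FLAG at the C terminus. Per the labels, whole hermaphrodite L2 larvae were taken 22 hours after synchronisation of starved L1 larvae, chromatin was sheared by sonication, and, in the description of both samples, the precipitation used an antibody against GFP. The antibody tag of both samples reads F13H6.1 instead. The description is followed here, but an antibody against the protein itself would also have bound untagged BCL-11, and the sources used here do not settle which was used. The labels number the replicates as separate biological replicates and give no batch or date that separates them.

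The values were used as deposited by the authors. There were 8 peak lists on 2 genome builds, ce11 and ce10. On each build these were the candidate peaks of replicate 1, those of replicate 2, those of both replicates pooled, and the optimal list after the IDR threshold. Per the text notes deposited with the lists, each candidate list came from alignments of the ChIP sample and of a control. Both replicates shared 1 control. Column 7 of the deposited lists is the signal, a value above 0 that the peak caller gave each peak relative to the control on a scale that the sources used here do not state. Column 9 of the deposited lists is the −log10 q of each peak, and it was not used in a test, because all peaks of the IDR list have the same value (2.59). The peak caller, the aligner and their versions are not given in the sources used here. Signal levels were not compared between lists, apart from the ratios of pooled to replicate signal given for mitochondrial and nuclear peaks, which were chosen after seeing the data. Peaks had been called in each replicate and in the pool, so the replicates were compared by overlap and rank. The IDR list was the 5133 strongest of the 30000 pooled candidates.

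The depth per sample is unknown, since the lists hold no read counts. Intervals are exact Clopper-Pearson intervals at 95% for shares and exact conditional intervals for odds ratios. They cover counting error over peaks or genes only and not the variation between animals. The shared control cannot be simulated without reads, so part of the overlap between replicates may come from it.

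Main results used the ce11 lists with the WBcel235 genome and the Ensembl release 115 annotation. A promoter window ran from 1000 bp upstream to 200 bp downstream of the 5′ end of any protein-coding transcript. Summits were assigned in the order promoter window, exon, intron, none of these. Genes with a summit in a promoter window are called bound. Replicate overlap took the 5133 strongest peaks of each replicate, counted an overlap of 1 bp or more, and was tested against 1000 circular shifts within each chromosome (one-sided permutation test). Locations and noncoding RNA genes (summit within 200 bp) were tested against 1000 random placements within the same chromosome (two-sided). Chromosome shares, gene lists, families and sequence patterns were tested with two-sided Fisher exact tests. Differences of mean log2 signal used two-sided permutation tests with 100000 resamples. Peaks within 20 kb of bcl-11 and unc-119 were compared with 10000 random positions (one-sided permutation test). Adjusted p values are Benjamini-Hochberg values within each family of tests, with a threshold of 0.05.

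The 22 gene lists held 478 entries, of which 466 matched a protein-coding gene by symbol and 12 did not match. The 26 families were defined by symbol patterns. Lists and families with fewer than 5 matched members were not tested. Sequence patterns (30, with a scrambled control) were searched on both strands within 100 bp of the summit. IDR peaks were compared with pooled candidates that overlap no IDR peak, drawn 1 to 1 in bins of 5 percentage points of GC content and of distance to the nearest 5′ end (up to 200 bp, up to 1000 bp, farther). A match was found for 5121 of 5123 nuclear peaks.

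Named genes followed a rule. They were the genes nearest to the 20 strongest IDR peaks (both genes of a divergent pair within 1000 bp), up to 4 bound members with the highest signal from each list or family past the threshold and from the neuronal, epidermal, SWI/SNF, NuRD and heterochronic lists whatever their p, and bcl-11 and unc-119. The lists, families, patterns, tests and naming rule were fixed before the data were examined, as were the alternatives, apart from those named here as chosen later. Alternatives tried were the stronger 50% of the IDR list, each replicate alone in place of the IDR list, promoter windows of 500 bp upstream and 100 bp downstream and of 2000 bp upstream and 500 bp downstream, genes with a candidate summit as background, and the nearest 5′ end at any distance. Others were 50% reciprocal overlap (with 100 shifts), summits within 100 bp, fewer or more of the strongest peaks, the ce10 lists, chromosome length as reference, pattern windows of 50 and 200 bp, other pattern backgrounds, noncoding distances of 0 and 500 bp, and distances of 10 and 40 kb from the transgene loci. Leaving out the mitochondrial peaks with the peaks near bcl-11, using only the most upstream 5′ end of each gene, leaving out weaker peaks that overlap a stronger one, and counting each pair of replicate peaks once, were chosen after seeing the data. The tests on peak strength, on the signal of ribosomal protein genes, on mitochondrial peaks and on symbol prefixes were also chosen after seeing the data. The tests of GAGAGA around bcl-11 and of explanations for peaks near tRNA genes were written for patterns already seen. They are not among the tests fixed beforehand. IDR values per peak are not in the lists, so the stricter threshold was the stronger 50% by signal. Each replicate alone stands for its strongest peaks, as many as the IDR list holds. This setting is called without the other replicate. A gene with no summit there can still have a weaker peak in the list of that replicate.

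The tests were tested on simulated data. With nothing planted, 0 of 200 gene lists were called, TGACCA was called in 0 of 20 runs, and the promoter share was called in 2 of 20 runs. Among the patterns not planted, apart from TGNCCA, there was 1 call over the 20 runs with nothing planted and there were 4 over the 20 runs with TGACCA planted. With 50% of a list bound, 183 of 200 lists were called, and all 20 runs with TGACCA planted at 5% of peaks and all 20 with 30% of peaks planted at promoters were called. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Read alignments were not used here.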

Results

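The data were 2 biological replicates of ChIP-seq for BCL-11, the C. elegans relative of the mammalian zinc finger repressors BCL11A and BCL11B. BCL-11 carried GFP and FLAG at its C terminus and was expressed from an integrated transgene in whole hermaphrodite L2 larvae, 22 hours after synchronisation. Both replicates formed 1 group, so no contrast between conditions could be made, and the question was where in the genome BCL-11 was found. The list that passed the authors' irreproducible discovery rate (IDR) threshold held 5133 peaks on ce11, with a median width of 420 bp, and covered 1.854 Mb. Some entries of that list overlap one another: 58 repeat the interval of another entry with a different summit, and 4942 remain when each weaker entry that overlaps a stronger one is left out. Replicate 1 alone had 28643 candidate peaks and replicate 2 had 27074. The lists hold no read counts, so the depth of each sample is unknown.

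The strongest BCL-11 sites were largely shared by the replicates. Of the 5133 strongest peaks of replicate 1, 4150 (80.8%) overlapped 1 of the 5133 strongest of replicate 2, against a mean of 3.91% and a maximum of 5.01% in random shifts (one-sided permutation test, p = 0.001, the smallest the shifts can give). In the other direction 4158 (81.0%) were shared. At rpl-3, which encodes a protein of the large ribosomal subunit, the promoter peak ranked 6 in replicate 1 and 2 in replicate 2. An intronic peak whose nearest 5′ end was that of lin-42, a gene related to period that times larval development, ranked 16 and 7. Over 5107 IDR peaks with an overlapping peak in both lists, the signal had a Spearman rho of 0.817 and a Pearson r of 0.880 on the log2 scale. Of these, 187 repeated the pair of replicate values of another peak, and over the 4920 distinct pairs rho was 0.803 and r 0.870. The IDR list held exactly the 5133 strongest pooled candidates, so replicate agreement can have set how many peaks were kept but not which. Among them, 17 overlapped no peak in the list of replicate 2 and 9 none in that of replicate 1. These correlations therefore hold for peaks selected by pooled strength. Over all overlapping peaks of the replicate lists rho was 0.778. These correlations are across peaks, which are not independent replicates, and both replicates were set against 1 control.

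**Figure D1:**
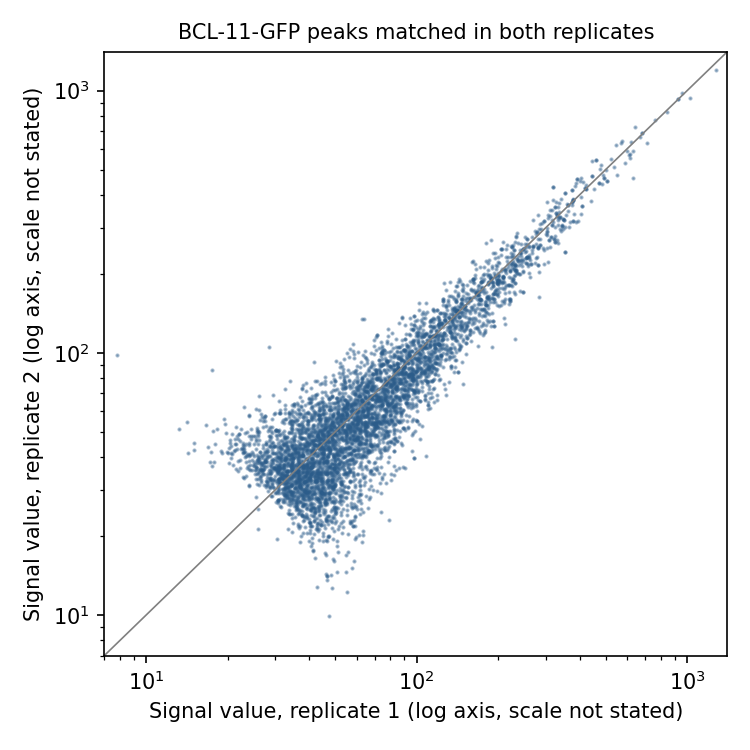
Signal of each IDR peak in replicate 1 (x axis) and replicate 2 (y axis), both as deposited and on log axes, with 1 point per IDR peak that overlaps a peak in both (5107 points, 187 of which repeat the values of another). The line marks equal values, and the points spread along it most widely at low signal, with a Spearman rho of 0.817.

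BCL-11 peaks lay mainly at promoters and rarely in exons. The promoter window ran from 1000 bp upstream to 200 bp downstream of a protein-coding 5′ end and held 2700 of the 5133 summits (52.6%, exact 95% interval 51.22 to 53.97%). Random placement put 25.8 ± 0.614% (SD of 1000 placements) there, a 2.04-fold difference. Exons outside those windows held 102 summits (1.99%, against 21.7% at random), introns held 861 (16.8%, against 27.4%), and the remaining 1470 (28.6%) fell in none of these, against 25.2% at random. All 4 shares differed from random placement (two-sided permutation tests, p = 0.002 each, the smallest the placements can give). With the wider window of 2000 bp upstream and 500 bp downstream, the last class was no longer above random placement (0.992-fold). The promoter share was 52.2% among the strongest peaks of replicate 1 and 52.3% among those of replicate 2, and it was 29.9% among the 23781 pooled candidates without an IDR peak.

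The X chromosome carried the densest set of BCL-11 peaks, at 65.0 per Mb (1151 peaks), followed by chromosome III at 60.1 per Mb (828 peaks). Chromosome V had the lowest density, 38.8 per Mb (811 peaks). X held 22.4% of the IDR peaks (exact 95% interval 21.3 to 23.6%) and 20.1% of the candidates without an IDR peak, an odds ratio of 1.15 (two-sided Fisher exact test, p = 0.0001719, adjusted p = 0.001031 over 6 chromosomes). Chromosome III held 16.13% against 17.7% (odds ratio 0.892, exact p = 0.006186, adjusted p = 0.01856). Neither difference passed the test in the stronger 50% of the list, where the odds ratio was 1.08 for X (exact p = 0.1251) and 0.908 for III (exact p = 0.08633). The comparison candidates of that test included the weaker IDR peaks.

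Among the 20 strongest peaks, 18 were nuclear and 2 mitochondrial, and 8 of the 20 lay on chromosome III. Ribosomal protein genes supplied 4 of them. The peak at III:3867285-3867826 had a signal of 1920 and its summit 280 bp upstream of rpl-3 (WBGene00004414), and the peaks upstream of rpl-15, rpl-35 and rpl-20 had signals of 1250, 1213 and 1185. The peak at II:10563401-10563755 (signal 1326) was 163 bp upstream of cdc-48.1, which encodes an AAA ATPase of protein quality control. The peak at III:4899670-4900161 (signal 1211) lay between tag-340 and nhl-2, the latter a cofactor of microRNA silencing. The promoter of bet-2, a bromodomain gene on X, had a signal of 1201, and the promoter shared by tasp-1 and K01G5.10 had 1335.

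Several of the strongest nuclear peaks were not at an annotated promoter. Introns held strong peaks whose nearest 5′ end was that of Y111B2A.12 (signal 2389), ppfr-1 (1669) or pqn-41 (2 peaks, 1532 and 1367). Another intronic peak lay 2984 bp upstream of its nearest 5′ end, that of lin-42 (II:1246827-1247300, signal 1358). The gene to which each intron belongs was not recorded. A peak whose nearest gene was sup-26, an RNA-binding protein gene, had a signal of 1846 and lay 1972 bp upstream. A peak whose nearest gene was sma-9, the Schnurri relative that acts in BMP signalling, lay 2971 bp upstream at X:10765990-10766667 (signal 1170). A weaker IDR peak lay closer to sma-9, 789 bp upstream (signal 286). The peak with Y37A1B.7 as its nearest gene (1950) was 10065 bp from the 5′ end of that gene. Peaks with W02H3.3 (1199) and F13D11.3 (1169) as nearest genes were also outside promoter windows. Y17G9B.5 and K11H12.8 shared the peaks of rpl-20 and rpl-15.

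BCL-11 summits were found in the promoter windows of 3084 of 19973 protein-coding genes (15.4%), and of 1738 genes when only the stronger 50% of the list was used. Of 2692 nuclear promoter summits, 651 (24.2%) lay in the windows of more than 1 gene and counted for each of them. Of the 22 gene lists, 9 differed from all other genes (Fisher exact tests, two-sided, adjusted over the 22 lists), 8 of them with more bound promoters and 1 with fewer. Body wall muscle genes stood out, with 19 of 30 bound (63.3%, exact 95% interval 43.9 to 80.1%; odds ratio 9.51, exact test, adjusted p = 7.803e-08). They included unc-60 (cofilin, signal 397), unc-112 (kindlin, 340.1), mup-2 (troponin T, 260) and mlc-2 (a myosin light chain, 227). Pan-neuronal genes were bound at 14 of 30 promoters (odds ratio 4.81, exact test, adjusted p = 0.0003876), among them syd-2 (liprin, 479), unc-108 (a Rab GTPase, 325), maco-1 (312) and rgef-1 (205).

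Genes for chromatin regulators and developmental timing were bound more often than other genes. Corepressor genes had 9 of 14 promoters bound (odds ratio 9.88, exact test, adjusted p = 0.0003876), including the SPEN relative din-1 (signal 533, with 6 summits), lin-9 (444), the retinoblastoma gene lin-35 (316) and the Groucho gene unc-37 (151). The NuRD and MEC list had 6 of 10 (odds ratio 8.23, exact test, adjusted p = 0.007096), with lin-40 (633), lin-53 (395), egl-27 (209.7, with 5 summits, or 3 without replicate 2) and mep-1 (136). The SWI/SNF list had 6 of 11 (odds ratio 6.58, exact test, adjusted p = 0.009696), with pbrm-1 (763), swsn-7 (399.9), swsn-3 (286) and swsn-6 (183). In the heterochronic pathway 8 of 13 promoters were bound (odds ratio 8.78, exact test, adjusted p = 0.00109), among them nhl-2, lin-66 (639.8), lin-28 (590.2) and lin-14 (441).

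Heat shock genes were bound at 8 of 17 promoters (odds ratio 4.88, exact test, adjusted p = 0.007683), with hsp-60 (signal 727), hsp-1 (544), hsp-3 (443) and hsp-110 (332, a peak shared with the proteasome gene rpn-3). The BMP and TGF-β list had 8 of 20 (odds ratio 3.66, exact test, adjusted p = 0.01939), with sma-9 (286), the SMAD gene sma-2 (269), tig-2 (122.4) and daf-3 (120.2). That call was lost without replicate 1 (odds ratio 2.97, exact test, adjusted p = 0.05796) and without replicate 2 (2.98, exact test, adjusted p = 0.05996). It was also lost in the stronger 50% of the list (3.50, exact test, adjusted p = 0.06995) and without weaker peaks that overlap a stronger one (2.96, exact test, adjusted p = 0.05827). None of 29 molting and apical matrix genes was bound, which allows a share of up to 11.9% (exact 95% interval; exact test, adjusted p = 0.04093). lin-42 is among those 29, and the strong peak whose nearest 5′ end was that of lin-42 lay outside its promoter windows. The molting call was lost in the stronger 50% of the list and with the narrower window of 500 bp upstream and 100 bp downstream. The odds ratio stayed 0 in both (exact tests, adjusted p = 0.3822 and 0.1169). The narrower window also ended the calls for the BMP, NuRD, SWI/SNF and heterochronic lists, and assigning summits to the nearest 5′ end ended those for the NuRD, SWI/SNF, heat shock and molting lists. Using only the most upstream 5′ end of each gene ended the BMP and molting calls.

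Fewer lists passed the test against a smaller set of comparison genes. Against the 7800 genes with any candidate summit at the promoter, 2 of 20 testable lists remained past the threshold. These were corepressors, with 9 of 10 bound (odds ratio 13.8), and body wall muscle, with 19 of 27 (odds ratio 3.65; exact test, adjusted p = 0.01512 for each). The pan-neuronal list had 14 of 23 (odds ratio 2.38, exact test, adjusted p = 0.1161) and the heterochronic, heat shock and BMP lists had 8 of 11 each (odds ratio 4.09, exact test, adjusted p = 0.08866). The NuRD list had 6 of 7 (odds ratio 9.19, exact test, adjusted p = 0.08866), the SWI/SNF list 6 of 9 (3.06, exact test, adjusted p = 0.3368) and the molting list 0 of 8 (0, exact test, adjusted p = 0.08866). The odds ratios of the corepressor, NuRD and BMP lists were not lower than against all other genes, and those of the other called lists with bound promoters were lower.

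Genes that specify or characterise other cell types were not called. Neuronal identity transcription factors had 2 of 40 promoters bound, unc-37 and egl-44 (odds ratio 0.288, exact test, adjusted p = 0.1425). The odds ratio was 0.446 without replicate 1 and 0.447 without replicate 2 (exact tests, adjusted p = 0.4029 and 0.4532), and with the nearest 5′ end it turned to 1.29. Neurotransmitter genes had 2 of 19 (snf-11 and unc-25), and epidermal regulators had 4 of 18, sma-9 and the weakly bound nhr-23, rnt-1 and blmp-1 (signals 70.73, 70.02 and 69.03). The setting without replicate 2 used only the strongest peaks of replicate 1, as many as the IDR list holds. The peaks at nhr-23 and rnt-1 ranked 5911 and 6279 in replicate 1 and fell outside these. The odds ratio of the epidermal list turned there from 1.56 to 0.690. Likewise, the peak at unc-25 ranked 5908 in replicate 2 and was left out without replicate 1. The odds ratio of the neurotransmitter list went there from 0.644 to 0.306. The HOX list had 5 of 12 (exact test, adjusted p = 0.05903), Wnt 8 of 26, pharynx 6 of 19, axon guidance 8 of 29, intestine 7 of 30, insulin and dauer signalling 4 of 21, germ line 3 of 30 and Notch and EGF 3 of 22. Glia had 0 of 15 and coelomocytes 0 of 11, which allow shares of up to 21.8% and 28.5%. Without replicate 2 the odds ratio fell from 3.92 to 1.84 for HOX (exact test, adjusted p = 0.6034) and from 2.53 to 1.47 for pharynx (exact test, adjusted p = 0.6717). Without replicate 1 it went from 0.865 to 0.262 for Notch and EGF and from 0 to 0.550 for the coelomocyte and head mesodermal list. The HOX, Wnt and axon guidance lists passed the test with the wider promoter window, and the HOX, axon guidance and pharynx lists with the nearest 5′ end.

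Ribosomal protein genes were the most often bound of the 26 gene families, at 65 of 83 promoters (78.3%, exact 95% interval 67.9 to 86.6%; odds ratio 20.2, exact test, adjusted p = 5.454e-36). Proteasome subunit genes followed with 17 of 33 (odds ratio 5.84, exact test, adjusted p = 6.454e-06), among them rpn-3 (signal 332, the peak shared with hsp-110), rpn-11 (224), pbs-1 (217) and rpt-2 (179.5). The proteasome call was lost in the stronger 50% of the list (odds ratio 2.83, exact test, adjusted p = 0.05542). Several large families were bound less often. Chemoreceptor genes had 18 of 1365 promoters bound (1.32%; odds ratio 0.0677, exact test, adjusted p = 1.906e-74), C-type lectins 4 of 240, cuticle collagens 6 of 175, F-box A genes 6 of 170 and major sperm proteins 0 of 43. The odds ratio of C-type lectins was 0.0916, and 0.140 without either replicate. Few genes of these families had a candidate summit of any kind at the promoter. These were 74 chemoreceptor genes, 41 C-type lectins, 44 cuticle collagens, 32 F-box A genes and 0 major sperm proteins. Of all 19973 protein-coding genes, 7800 had one. Members of a family share sequence, so mapping of their promoters can be uncertain, and its part in these low shares was not tested.

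Cytochromes P450 (2 of 74), neuropeptide-like proteins (3 of 71), warthog, groundhog and ground-like genes (2 of 59) and FMRFamide-like peptides (0 of 31) were the other families called, all with fewer bound promoters. The call for neuropeptide-like proteins (odds ratio 0.241) was lost without replicate 1 (0.416, exact test, adjusted p = 0.07865), while without replicate 2 none was bound (0, exact test, adjusted p = 6.024e-05). The replicate 1 peaks at nlp-4 (rank 7333) and at nlp-31 and nlp-34 (rank 6326) fell outside the strongest peaks used there. The warthog group (0.192) lost its call without replicate 2 (0.295, exact test, adjusted p = 0.06634) and kept it without replicate 1 (0.294, exact test, adjusted p = 0.04873). P450 genes went from 0.152 to 0.314 without replicate 1 (exact test, adjusted p = 0.04159). In the stronger 50% of the list the calls for P450 genes, major sperm proteins and FMRFamide-like peptides were lost, though the odds ratios there (0.143, 0 and 0) were no higher. FMRFamide-like peptides also lost theirs with the narrower window, again with an odds ratio of 0. The calls for major sperm proteins and FMRFamide-like peptides were lost with the nearest 5′ end (odds ratios 0.332 and 0.147). srh-2 was the most strongly bound chemoreceptor gene (signal 560, with 3 summits), col-38 the most strongly bound collagen gene (266) and fbxa-83 the most strongly bound F-box A gene (248). Against genes with a candidate summit, ribosomal proteins (odds ratio 6.75), proteasome subunits (2.90), chemoreceptors (0.488), C-type lectins (0.164) and cuticle collagens (0.240) stayed past the threshold, and histones (3.07) and ceh homeobox genes (0.305) passed it only there among the comparisons tried. The calls for F-box A genes (0.352, exact test, adjusted p = 0.05032), P450 genes (0.218), neuropeptide-like proteins (0.269), the warthog group (0.218) and FMRFamide-like peptides (0) were lost there. Major sperm proteins could not be tested there, since none had a candidate summit.

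**Figure D2:**
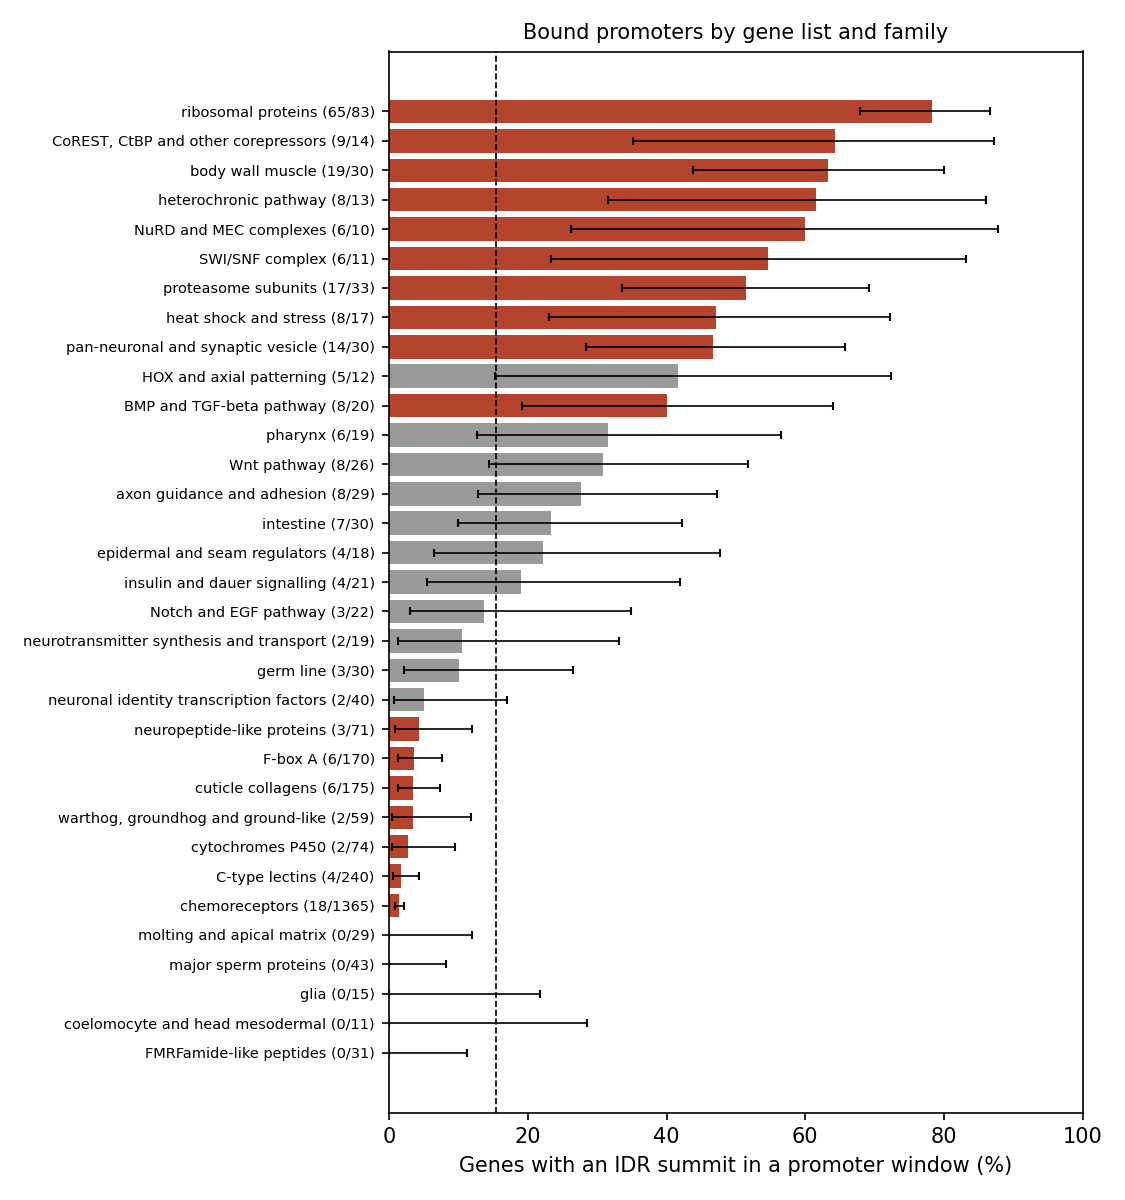
Percent of genes with a BCL-11 summit in the promoter window (x axis) for the 22 gene lists and the 11 families past the threshold, with exact 95% intervals (red, past the threshold; dashed line, all protein-coding genes). Body wall muscle (63.3%) and ribosomal protein genes (78.3%) stand above the 15.4% of all protein-coding genes, and chemoreceptors (1.32%) stand below it.

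BCL-11 peaks were frequent near tRNA, snoRNA, snRNA and lincRNA genes. A summit lay within 200 bp of 194 of 612 tRNA genes (31.7%, exact 95% interval 28.0 to 35.6%), against 2.61 ± 0.685% (SD) in random placement. The shares were 26.6% for snoRNA genes (92 of 346), 17.1% for snRNA genes (22 genes) and 13.9% for lincRNA genes (27 of 194), against 2.62%, 2.41% and 7.86%. These 4 of 6 classes passed the test (two-sided permutation tests, adjusted p = 0.003996, or 0.01499 for lincRNA). Whether neighbouring protein-coding promoters account for the snoRNA, snRNA and lincRNA shares was not tested. The tRNA class alone passed when the summit had to lie inside the gene. The shares were then still 2.57 times random placement for snoRNA, 4.08 times for snRNA and 1.56 times for lincRNA genes (permutation tests, adjusted p = 0.1289 each). miRNA genes (13 of 261) passed without replicate 1 (permutation test, adjusted p = 0.01678) and without replicate 2 (permutation test, adjusted p = 0.01439) but not in the IDR list (permutation test, adjusted p = 0.07433), and 0 of 20 rRNA genes had a summit.

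TGACCA, the site bound by the zinc fingers of mammalian BCL11A, was not more frequent at BCL-11 summits. It occurred within 100 bp of 401 of 5121 summits (7.83%) and of 427 of 5121 matched candidates (8.34%), an odds ratio of 0.934 with a 95% interval of 0.808 to 1.08 (two-sided Fisher exact test, p = 0.3648). It ranked 1067 of 2080 6-mers, and its scrambled control ACCAGT had an odds ratio of 0.940. The looser pattern TGNCCA was less frequent at summits than at matched candidates (odds ratio 0.832, exact p = 0.0001326), but not past the threshold without replicate 1 (0.932, exact test, adjusted p = 0.2135), and it turned to 1.11 against windows 500 bp to either side. Against those windows the direction turned for TGACCA too (odds ratio 1.25, exact p = 0.0007955) as it did for the scrambled control (1.27).

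GA-rich sequence was more frequent at BCL-11 summits than at matched candidates, which were weaker peaks of the same experiment. GAGAGA was present at 2392 summits (46.7%) and 1120 matched candidates (21.9%), an odds ratio of 3.13 (95% interval 2.87 to 3.42; exact test, adjusted p = 2.149e-155), and it ranked 1 among the 6-mers. GAGACGC, a site like that of the zinc finger protein EOR-1, was present at 16.19% against 5.68% (odds ratio 3.21, exact test, adjusted p = 5.02e-66), and GAGAGAGAGA at 7.81% against 2.23% (odds ratio 3.72). The odds ratio of GAGAGA was 3.15 in replicate 1 and 2.88 in replicate 2, and it was 7.82 against windows 500 bp to either side. No other factor and no strain without the tag was compared here. Whether the GA-rich sequence or the promoter locations are particular to BCL-11 was therefore not tested. GAGAGA was present at 580 of the 1024 strongest nuclear peaks (56.6%) and 390 of the 1025 weakest (38.05%; two-sided Fisher exact test, p = 3.491e-17), a comparison chosen after the data were seen. It was not matched for GC content or distance to a 5′ end. The promoter share also differed, at 58.0% of the strongest and 47.5% of the weakest peaks.

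Of 30 patterns, 18 passed the test, 10 more frequent and 8 less frequent at summits, and 11 passed in the stronger 50% of the list. The forkhead site TGTTTAC (odds ratio 2.14) and the PHA-4 site TGTTTGC (1.98) were more frequent, as was CACGTG (1.44), while the ETS site CCGGAAR (0.491), TTTCAG (0.548) and the homeodomain core TAATTA (0.600) were less frequent. TGTTTAC did not pass in the stronger 50% (odds ratio 1.38, exact test, adjusted p = 0.1045). The GATA site TGATAA (1.29) turned to 0.922 there. In the stronger 50% the comparison candidates included the weaker IDR peaks, so these values in part set strong against weaker IDR peaks. Candidates were not matched for exons and introns. Before matching, exons held 19.5% and introns 27.7% of the candidates without an IDR peak, against 1.99% and 16.8% of IDR peaks. This difference could change the share of a pattern, such as the splice acceptor pattern TTTCAG, and its part was not tested.

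**Figure D3:**
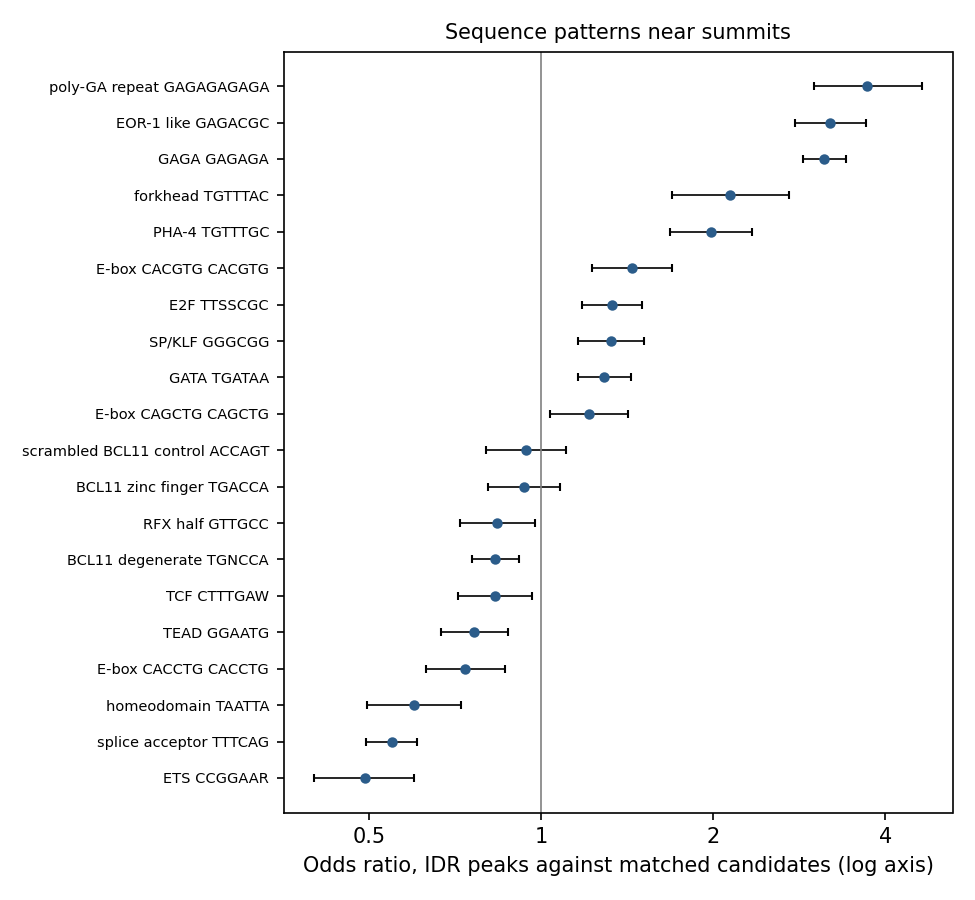
Odds ratio of the 18 sequence patterns past the threshold, of TGACCA and of its scrambled control at BCL-11 summits against matched candidates (x axis, log scale), with 95% intervals. GAGAGA (3.13), GAGACGC (3.21) and GAGAGAGAGA (3.72) lie farthest above 1, and TGACCA (0.934) has an interval that includes 1.

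Peaks at promoters had slightly higher signal than peaks elsewhere. The mean log2 signal was 7.02 ± 0.88 (SD, n = 2700 peaks) at promoters and 6.92 ± 0.87 (n = 2433) elsewhere, a difference of 0.10 (two-sided permutation test, p = 4e-05). The difference was 0.44 in the full list of replicate 1 and 0.40 in that of replicate 2 (permutation tests, p = 1e-05 each, the smallest they can give). It did not pass in the stronger 50% of the IDR list (0.0342, permutation p = 0.2557) or with the wider promoter window (0.0328, permutation p = 0.2131). Ribosomal protein genes had a median signal of 183 over 65 bound genes, against 118.5 over 3019 other bound genes (two-sided permutation test, p = 1e-05, the smallest it can give, chosen after the data were seen).

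The bcl-11 gene itself, which the transgene carries, lay in a dense block of peaks. Within 20 kb of bcl-11 (V:6356025-6362997) there were 19 IDR peaks between V:6341085 and V:6366012, against a mean of 2.38 and a 95th percentile of 7 around random positions (one-sided permutation test, p = 0.0004). Their signals ran from 65.0 to 394, and 11 of the 19 lay outside promoters, exons and introns. Replicate 1 had 30 candidates there and replicate 2 had 34. The nearest other IDR peaks were 64.6 kb to the left and 47.02 kb to the right. A window of the same length on chromosome II held 21 IDR peaks. unc-119 (III:10902641-10908935), whose mutation the strain carries, had 1 IDR peak within 20 kb, in an intron (signal 105; one-sided permutation test, p = 0.7825).

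**Figure D4:**
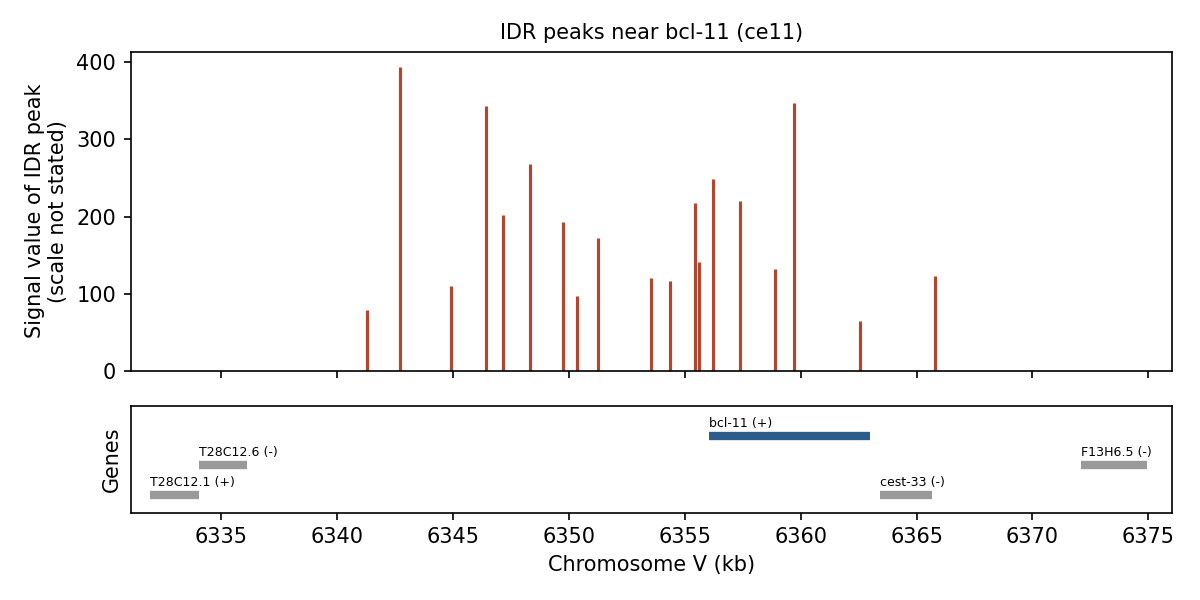
Signal of IDR peaks (y axis, as deposited) along chromosome V (x axis, position in kb on ce11) around bcl-11, with a bar at each summit and protein-coding genes drawn to scale. The 19 peaks fall between V:6341085 and V:6366012.

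The mitochondrial genome held 10 IDR peaks, with signals from 131 to 4868, and the strongest, at M:12164-12611, was the strongest peak of the whole list. They covered 3006 of 13794 bp (21.8%). Replicate 1 listed 16 mitochondrial peaks and replicate 2 listed 0.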

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

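The alternatives without mitochondrial peaks and peaks near bcl-11, with only the most upstream 5′ end, without weaker peaks that overlap a stronger one, and with each pair of replicate peaks counted once, were chosen only after the results were seen. Of 1331 recomputed values, 1146 kept their direction and side of the threshold, or their size within the set limits. 71 were weaker, 31 stronger, 36 reversed and 47 moved. The 1331 values include 483 checks that a named gene still had a summit, of which 444 did. They also include ranks of the strongest peaks, whose limits spanned the whole list, so these could only be kept. The share kept is therefore not a measure of how stable the tests were. The replicate overlap stayed far above random shifts in every alternative run, and the promoter share stayed above random placement, from 41.2 to 68.7%. The rank correlation was 0.778 over all overlapping peaks and 0.803 with each pair counted once. In the stronger 50% of the list, the X odds ratio was 1.08, bound genes numbered 1738, called patterns 11, and the promoter difference was 0.0342 (log2). Fewer peaks remained there by construction, and for X and the patterns the comparison candidates included the weaker IDR peaks. With the wider promoter window that difference was 0.0328. List calls fell to 4 with the narrower window and to 2 against genes with a candidate summit, where family calls fell to 7 from 11. Fewer genes were tested there by construction. With the wider window 12 lists and 16 families were called, without replicate 1 15 families, and against flanking windows 24 patterns. V-type ATPase genes were called in 5 of 10 alternatives and insulin-like peptides in 4, but neither in the IDR list. At 0 bp, 1 noncoding class was called. TGACCA had odds ratios from 0.966 to 1.06 without a replicate, 1.03 in the stronger 50%, 1.16 within 50 bp, 1.25 against flanking windows and 1.07 without matching, and TGNCCA had 0.832 with matching and 1.11 against flanking windows. Directions also turned in the stronger 50% for HOX (0.954), Notch and EGF (1.05), epidermal (0.617), germ line (1.17), intestine (0.749) and GATA (0.922). They turned with the wider window for Notch and EGF (1.81) and for summits in no class (0.992), with the narrower window for insulin (0.761), and with the nearest 5′ end for Notch and EGF (2.54), neuronal identity (1.29) and neurotransmitter genes (1.18). Epidermal regulators ranged from 0.690 to 1.57 without a replicate, and histones from 0.687 to 1.104. With the nearest 5′ end ceh homeobox genes (1.04), histones (0.632) and patched-related genes (1.33) turned, in the stronger 50% nuclear hormone receptors (0.934), and against genes with a candidate summit nuclear hormone receptors (0.991) and ztf genes (0.983). Against flanking windows GATA (0.958), CACCTG (1.17), RFX (1.36), TEAD (1.02) and the scrambled control (1.27) turned, and without matching GATA (0.961), RFX (1.20) and the scrambled control (1.08). The scrambled control also turned within 50 bp (1.07) and without mitochondrial and bcl-11 peaks (1.06). Among families called in no setting and patterns and chromosomes not called, which were left out of the counts above after their values were seen, 34 of 168 recomputed odds ratios turned direction, and 3 of these passed the threshold in the alternative. Except where stated, the cause was not tested. Each matched background is a random draw, and draws were not repeated. Depth is unknown, so it cannot be said which weak sites were missed.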

Other observations

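The tests on mitochondrial peaks, on symbol prefixes and on GAGAGA in the bcl-11 block (its Fisher exact test) were chosen only after the results were seen. The GAGAGA shares around bcl-11 and the tests on tRNA genes were set up to explain peaks already seen.

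The 19 peaks around bcl-11 could come from extra copies of transgene DNA, which give more fragments with or without binding. GAGAGA occurred at 47.4% of them (9 of 19, exact 95% interval 24.4 to 71.1%), against 21.9% of matched candidates and 46.7% of the other IDR peaks. This argues against copies that raise peaks with the sequence of the matched candidates. Those candidates were matched to the whole IDR list and not to this block. The test also cannot tell binding from GA-rich sites raised by extra copies without binding. A GA-rich block is argued against as well, since 19.3% of 88 windows of the block away from the summits held GAGAGA (two-sided Fisher exact test, p = 0.01666). Extra copies that raise weak but real sites remain open, because the lists hold no reads from which copy number could be measured. No biological explanation was tested, since the design has 1 group.

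The 16 mitochondrial peaks in the list of replicate 1 were strong there (signal 144.5 or more, against a median of 13.8), and replicate 2 listed 0. Of 578 nuclear replicate 1 peaks with a signal of 144.5 or more, 0% were missing from the list of replicate 2 (exact 95% interval 0 to 0.636%), and 0.137% of the nuclear IDR peaks were, but both sets are strong by selection and do not test a general lack of weak peaks in replicate 2. The pooled signal of 9 mitochondrial IDR peaks was 0.853 to 1.65 times that of the replicate 1 peak within 100 bp, below the nuclear median of 1.94, while the pooled signal of nuclear IDR peaks was a median of 1.00 times the sum of both replicates (5th to 95th percentile 0.943 to 1.08, 4941 peaks). Sites bound in both replicates, peaks too weak for the list of replicate 2, removal of mitochondrial reads before its peaks were called (which would give 0 whatever was bound) and a difference in mitochondrial reads between the libraries cannot be told apart, since the lists hold no reads. No biological explanation was tested.

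Peaks near tRNA genes could reflect reads shared between identical genes or the promoters of neighbouring genes. Of 140 tRNA genes whose sequence occurs once in the genome, 20.7% had a summit within 200 bp (exact 95% interval 14.3 to 28.4%; 2.61% at random). Of 463 tRNA genes outside promoter windows, 31.3% did (2.68% at random). These shares argue against either explanation alone as the whole cause, and both acting together were not tested. Occurring once means no exact copy of the gene, so reads shared with nearly identical genes are not covered. Genes with repeated sequences had a summit more often (165 of 472, 34.96%; two-sided Fisher exact test against the 140, p = 0.001323), so shared reads may still add to the pattern. Open chromatin at tRNA genes, which gives signal in many ChIP experiments, remains open and was not tested. No biological explanation was tested.

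Among 175 symbol prefixes with 10 or more genes, 49 differed from other genes in bound promoters (Fisher exact tests, adjusted), 20 with more and 29 with fewer. Nucleoporin genes (npp) had 14 of 26 bound and, against genes with a candidate summit, 14 of 17 (odds ratio 7.16, two-sided Fisher exact test, adjusted p = 0.01385). On that background npp, rpl and rps passed of the 20 prefixes with more bound promoters, and 17 did not, among them eif (adjusted p = 0.1148, exact test), dnj (0.122) and taf (0.7146). Of the 29 with fewer, 14 could be tested there and clec and col passed.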
